A study of Homo sapiens with 6 samples.

How the data were processed

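Total RNA of the myeloma cell line JJN3 was measured on 6 Affymetrix U133 Plus 2.0 arrays, 3 with a CKS1B shRNA and 3 with a scrambled shRNA, and the groups were taken from the labels. The deposited values are linear intensity values, 1 per probe set and array, made by the authors with MAS5 per the submitters' processing notes. The version and parameters of MAS5 are not given in the sources used here. The deposited intensities had the same 2% trimmed mean, 500, on every array to within 0.1 units, and no other normalization between arrays was visible in them. A trimmed-mean scaling equalises the mean of an array but not the width of its distribution, so an array with a compressed scale keeps it.

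The table held 54675 probe sets, of which 62 control probe sets were left out of the tests. Of the other 54613, 41091 were named with 1 gene symbol, 1801 with several genes and 11721 had no name here. Names came from the platform annotation paired with the table. Over the whole annotation, before control probe sets were left out, Entrez identifiers of 41043 probe sets with 1 symbol matched the RefSeq gene table of assembly GRCh38.p14, and 54 did not. That table was used for current symbols only. No gene was named from a probe set with several genes, and no coordinates were used since no build is named in the files. Values were turned into log2(value + 16). Probe sets below the median mean log2 value (7.34, a value of about 146) were left out, and the brightest probe set over the arrays fitted was kept for each gene, which left 12663 of 19775 genes with 6 arrays.

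The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), without further normalization or covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. For CKS1B a two-sided exact permutation test of 3 arrays against 3 was added. The 27 gene lists were tested with camera at a preset correlation between genes of 0.01 where at least 5 genes were tested, which held for 25 lists, and adjusted over those lists. Of the 528 genes in the lists, 48 were not named on the array. Each list's median was also set against 10000 random lists of the same size matched on mean expression in 20 bins. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

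The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took CKS1B, SKP2, CDKN1B, CKS2, CCND2 and MAF, up to 12 genes past the threshold in each direction, the 10 genes of smallest p in each direction if fewer than 10 passed, and per list up to 4 members past the threshold or the 2 of smallest p. The alternatives were pseudocounts of 1 and 64, no filter and a filter at the 70th percentile, centring on the median, quantile normalization, the letter in the title as a block, eBayes without the trend, array weights, the mean of a gene's probe sets, only probe sets without a suffix for shared sequence, all probe sets, a test of each gene on its own spread, other thresholds, an estimated correlation, fry, and leaving out each array or each letter. Added after the data were seen were quantile normalization without CKS1B shRNA array B, an estimated correlation without that array, the letter as a block without that array, and leaving out both that array and scrambled array C. A group of 2 arrays left in this way shares its estimate of the spread with the other group.

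The scripts were tested on simulated data of 12663 genes with the spread of each array, in 10 runs with 200 changed genes each. With 6 arrays the fit recovered 0.3% of genes changed by 1 log2 unit, 31.8% of those changed by 2 and 93% of those changed by 4, with 0 false calls among 829. Without CKS1B shRNA array B it recovered 46.6%, 100% and 100%, with 63 false calls among 1745. A list of 30 genes shifted by -0.7 was called in 10 of 10 runs and 0 of 240 unshifted lists were called. All simulated genes of an array shared the same spread, and they varied independently of each other. Real genes differ in spread: without CKS1B shRNA array B the SE was 0.46 for ZNF335 and 0.22 for RDX. ZNF335, at a log2 difference of 2.23, had an adjusted p of 0.274 in limma there. The shares recovered and the false calls therefore need not hold for the real genes. Genes of the real lists of G1/S and G2/M had estimated correlations of 0.246 and 0.293 with 6 arrays. These runs therefore do not measure the rate of false calls among lists whose genes vary together.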

Results

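Gene expression was measured in JJN3, an established human myeloma cell line, on 6 Affymetrix U133 Plus 2.0 arrays. On 3 arrays the cells carried a short hairpin RNA (shRNA) against CKS1B, and on the other 3 a scrambled shRNA with no specific target, both delivered by viral transduction. CKS1B is a small partner of cyclin-dependent kinases and a cofactor of the SCF-SKP2 ubiquitin ligase, which marks the kinase inhibitor CDKN1B (p27) for degradation. The comparison asks which transcripts differ when CKS1B is lowered. Levels are MAS5 values on a linear scale, given as mean ± SD over the 3 arrays of a group (n = 3) unless stated. Differences are CKS1B shRNA minus scrambled shRNA on the log2(value + 16) scale, which understates the change of dim genes. The arrays of each group bear the letters A, B and C, and the title of scrambled array B carries an additional word that the labels do not explain. No label says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical, and their number limits the precision.

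CKS1B shRNA array B stood apart from the other 5 arrays. Across the 54613 probe sets other than controls, which are not independent replicates, its Pearson correlation with the others lay between 0.577 and 0.610. Among the other 5 it was 0.879 to 0.958. The SD of its log2 values was 1.61, against 1.83 on scrambled array C and 2.19 to 2.24 on the remaining arrays. Its median value was 334, against 201.8 on scrambled array C and 117.5 to 136.3 elsewhere. The ratio of the 3' to the 5' control probe set of actin, which rises when RNA is degraded or labelled mainly at its 3' end, was 12.4 on this array. It was 1.05, 1.15 and 1.66 on scrambled arrays A, B and C, and 1.11 and 2.93 on CKS1B shRNA arrays A and C. The same ratio for GAPDH was 4.70 on array B and 0.98 to 1.18 on the others. All 6 arrays entered the main comparison, and each leading result is also given for the 5 arrays left without CKS1B shRNA array B.

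**Figure D1:**
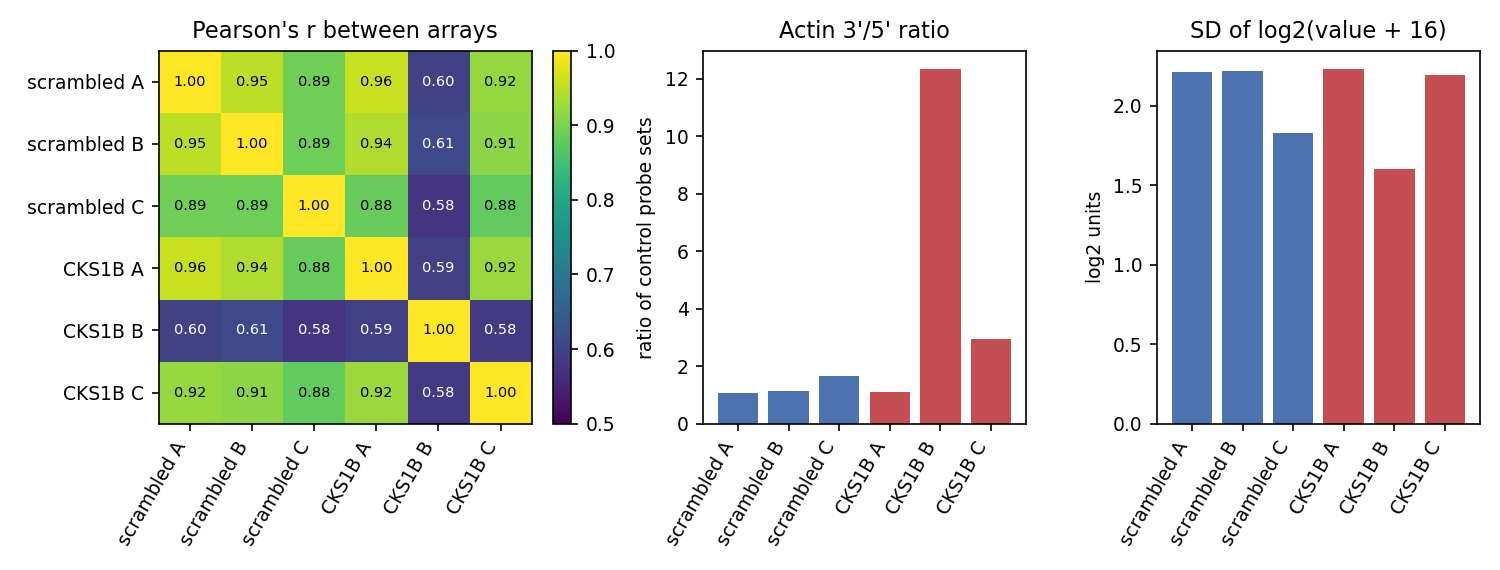
Pearson's r between arrays across the 54613 probe sets other than controls (left), the actin 3'/5' ratio (middle) and the SD of log2 values of those 54613 probe sets (right, log2 units) for each of the 6 arrays, with scrambled shRNA in blue and CKS1B shRNA in red bars. CKS1B shRNA array B has the lowest correlations (0.577 to 0.610), the highest actin ratio (12.4) and the smallest SD (1.61).

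CKS1B itself was lower on every CKS1B shRNA array than on any scrambled array. Its only probe set read 8266, 8441 and 7294 on scrambled arrays A, B and C, a mean of 8000 ± 618 (SD, n = 3). It read 481, 269 and 828 on the CKS1B shRNA arrays, a mean of 526 ± 282 (SD, n = 3), which was 6.57% ± 3.52 of the scrambled mean. The log2 difference was -4.02 (SE 0.44), or 16.2-fold lower. A two-sided exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The adjusted p from limma over all genes was 0.246 with 6 arrays. Without CKS1B shRNA array B the difference was -3.63 (SE 0.26), 12.4-fold lower, with an adjusted p of 0.00135. On array B bright genes as a whole read low: the 500 genes nearest to CKS1B in scrambled mean had a median of 1731 there, against 6991 to 8760 on the other arrays. Of these 500 genes, 58.2% to 66.8% read at or below CKS1B on the scrambled arrays, 0% on CKS1B shRNA arrays A and C, and 4.8% on array B.

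Without CKS1B shRNA array B, 6 of 12612 genes passed an adjusted p of 0.05 in limma, 3 of them lower and 3 higher with the CKS1B shRNA. Beside CKS1B, RDX (radixin, which ties actin filaments to the plasma membrane) and SLC39A10 (a zinc importer) fell, and NCKAP1 (a subunit of the actin-regulating WAVE complex), CTSC (the lysosomal protease cathepsin C) and FTH1P5 rose. RDX read 2685 ± 142 with the scrambled shRNA and 803 ± 94.0 with the CKS1B shRNA (SD, n = 3), and all 3 CKS1B shRNA arrays lay below all scrambled arrays. Its log2 difference was -1.73 (SE 0.30) with 6 arrays and -1.80 without array B (adjusted p = 0.0400). SLC39A10 read 1340 ± 210 and 358.5 ± 261, a log2 difference of -2.07 (SE 0.49) that was -2.60 without array B (adjusted p = 0.0362). NCKAP1 read 386 ± 97.3 and 1580 ± 947, with only 489 on array B, and its log2 difference of 1.74 (SE 0.58) was 2.44 without that array (adjusted p = 0.0362). With quantile normalization and without array B, RDX, SLC39A10, NCKAP1 and CTSC no longer passed (adjusted p = 0.0578 for each), with log2 differences of -1.80, -2.50, 2.53 and 1.40. Without both arrays of letter B only CKS1B passed, and without array B and scrambled array C 0 genes did (CKS1B adjusted p = 0.0604). These genes were chosen after their values were seen, apart from CKS1B, RDX and SLC39A10, which the rule for named genes also took.

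For CTSC and FTH1P5 the probe sets limit the reading. CTSC rose by a log2 difference of 1.58 (adjusted p = 0.0483) through the probe set that was brightest without CKS1B shRNA array B. The probe set brightest over all 6 arrays gave -0.04 with 6 arrays and 0.72 without array B. The other 2 probe sets gave 0.31, with the groups overlapping, and -0.18 without array B. FTH1P5 is a pseudogene of the ferritin heavy chain, and its probe set is of a class that can bind several related transcripts. Its log2 difference was 2.64 without array B (adjusted p = 0.0483) and 0.56 with all 6 arrays, since array B read 277 against a mean of 22890 on CKS1B shRNA arrays A and C.

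With all 6 arrays, 0 of 12663 genes were higher and 0 lower at an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 373 genes, 151 higher and 222 lower, where chance alone would give 633. A test of each gene on its own spread gave 539 genes unadjusted and 0 adjusted. In 1437 genes (11.3%) the groups did not overlap, and chance gives 10%. Without CKS1B shRNA array B, 1217 genes passed an unadjusted p of 0.05, against 631 by chance. The groups then did not overlap in 3565 genes (28.3%), where chance gives 20%.

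The 10 genes of smallest p in each direction are given as values, since all but CKS1B had an adjusted p of 0.933. Higher with the CKS1B shRNA were GPC6, ZNF335, MYO1D, YES1, C11orf54, XIAP, LOC100996756, HK1, C21orf91 and ZCCHC2, with log2 differences from 1.23 to 2.17. GPC6, a cell-surface heparan sulfate proteoglycan, read 374 ± 18.1 and 1081 ± 108 (log2 1.49). MYO1D, an unconventional myosin, read 323 ± 23.9 and 826 ± 79.5 (log2 1.31). YES1, a kinase of the Src family, read 1180 ± 84.2 and 4453 ± 2412 (log2 1.78, and 1.36 without CKS1B shRNA array B), while its other probe set read 497 on array B against a scrambled mean of 1193. XIAP, an inhibitor of caspases, read 628.5 ± 163.5 and 1793 ± 593.5 (log2 1.47). Lower, beside CKS1B, RDX and SLC39A10, were MAP3K21, MFN1, B3GALNT2, FLI1, CDC26, NSUN2 and TMEM65, with log2 differences from -1.69 to -1.19. MFN1, which fuses mitochondrial outer membranes, read 926 ± 259 and 297 ± 32.9 (log2 -1.55). FLI1, a transcription factor of the ETS family, read 1724 ± 673 and 514 ± 122 (log2 -1.66). CDC26, a subunit of the anaphase-promoting complex, read 1963 ± 102 and 732 ± 316 (log2 -1.48). In each of these genes all 3 arrays of a group lay on the same side of all 3 of the other.

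**Figure D2:**
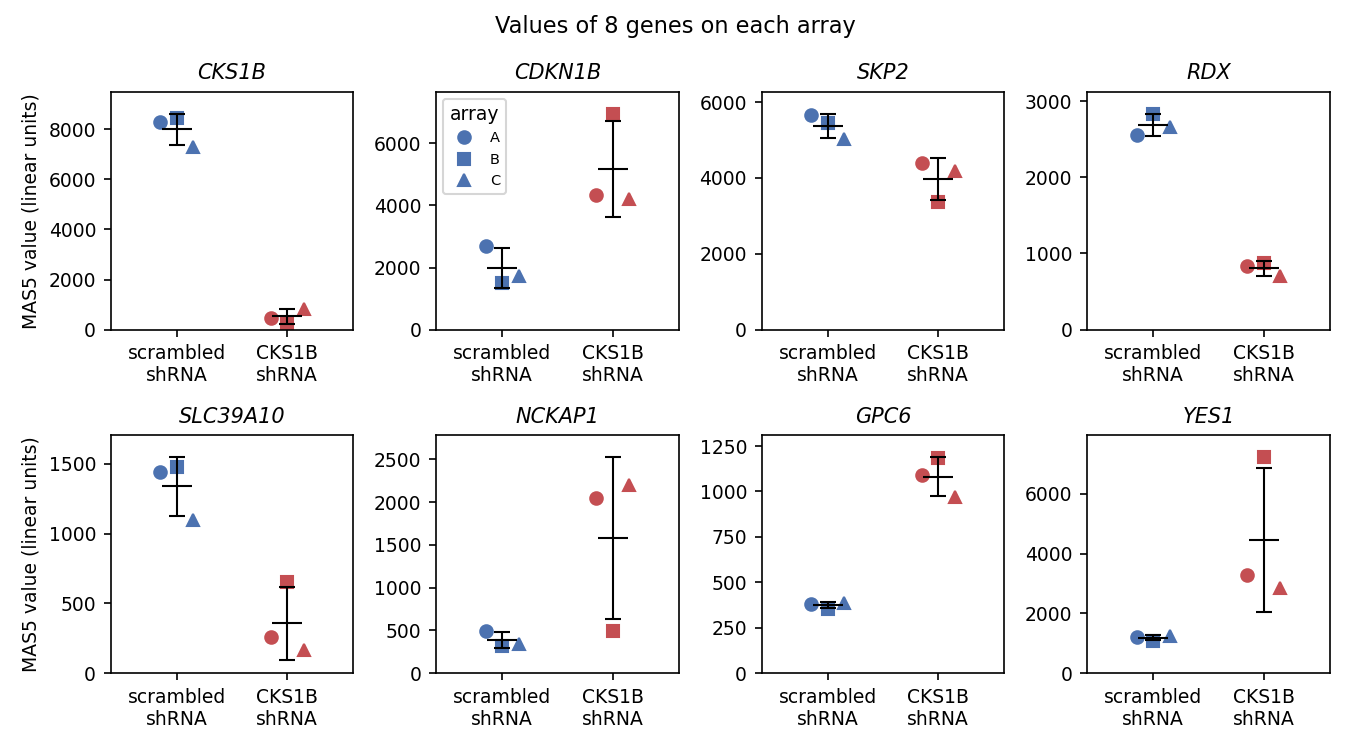
MAS5 values (linear units, each panel on its own axis from 0) of 8 genes on the 6 arrays, with circles, squares and triangles for arrays A, B and C, and the mean and SD of each group (n = 3) in black. CKS1B, SKP2, RDX and SLC39A10 lie lower on every CKS1B shRNA array, CDKN1B, GPC6 and YES1 higher, and NCKAP1 overlaps only through CKS1B shRNA array B (489).

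Among the direct partners of CKS1B, CDKN1B read higher and SKP2 lower on all 3 CKS1B shRNA arrays than on any scrambled array. This holds for the probe set used for each, with neither past the threshold over all genes. The groups did not overlap in 11.3% of all genes tested, where chance gives 10%. The arrays measure transcripts, so these values do not measure the CDKN1B protein that SCF-SKP2 marks for degradation. CDKN1B read 1976 ± 646 with the scrambled shRNA and 5169 ± 1550 with the CKS1B shRNA, a log2 difference of 1.39 (SE 0.41, adjusted p = 0.933) that was 1.15 without CKS1B shRNA array B. SKP2, the F-box protein that binds CDKN1B, read 5376 ± 321 and 3976 ± 545 (log2 -0.44, SE 0.37, adjusted p = 0.933), while another SKP2 probe set read 3126 on array B against a scrambled mean of 2539. CKS2, the paralog of CKS1B, read 7709 ± 1105 and 7930 ± 5554, and its log2 difference went from -0.29 to 0.45 without array B. The list of the SCF-SKP2 complex and CDK2 partners did not pass camera, limma's test of a list against all other genes (15 tested, 7 higher and 8 lower, adjusted p = 0.275). Nor did the list of CDK inhibitors and pocket proteins (8 tested, 5 higher and 3 lower, adjusted p = 0.275). Over all genes 0 members of any list passed with 6 arrays, and adjusted over the list alone CKS1B and XIAP did. That adjustment does not account for the number of lists. XIAP passed through a probe set that read 2325 on array B, while another read 139.5 there against a scrambled mean of 243.7. A further XIAP probe set read 229.7 on array B against 287.7, and the rest read above their scrambled means. Without array B, CKS1B passed over all genes, and adjusted over the list alone CKS1B, CDKN1B, SESN1 and XIAP passed.

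Lists of cell cycle genes passed camera as lower at the preset correlation, though most of the size came from CKS1B shRNA array B. In 5 of the 10 ways to split the 6 arrays, the real one included, at least as many lists passed. The calls therefore do not set the real groups apart from other groupings. Of the list of G1/S and DNA replication, 33 of 40 genes were lower and 7 higher, with a median log2 difference of -0.735 (camera adjusted p = 0.000192). Of the list of G2/M and mitosis, 31 of 37 were lower and 6 higher, with a median of -0.555 (adjusted p = 0.00269). With an estimated correlation between genes neither call held (adjusted p = 0.757 for each). POLE2, a subunit of the leading-strand DNA polymerase, read 2580 ± 215 and 1236 ± 821 (log2 -1.26). GINS3, of the replicative helicase, read 1454 ± 415 and 731 ± 265 (log2 -1.02). NEK2, a mitotic kinase, read 2401 ± 382 and 1543 ± 575 (log2 -0.68). CDK1, the kinase that drives entry into mitosis, read 5939 ± 366 and 2870 ± 2508 through its brightest probe set, which read 350.5 on array B, while another CDK1 probe set read 4386 there. Adjusted p was 0.933 for each of these 4 genes. On array B the median of the G1/S list lay -1.47 log2 units from the scrambled mean relative to all genes, against -0.20 on array A and -0.15 on array C. The scrambled arrays, each set against the other 2, spanned -0.16 to 0.08. For G2/M the shifts were 0.08, -1.21 and -0.58 on CKS1B shRNA arrays A, B and C, and -0.40 to 0.27 on the scrambled arrays. Without array B, 28 of 40 G1/S genes were lower (median -0.154, adjusted p = 0.0327) and 27 of 37 G2/M genes (median -0.271, adjusted p = 0.0272), with adjusted p of 0.511 and 0.741 with an estimated correlation. Without both arrays of letter B neither call held (adjusted p = 0.174 for G1/S, median -0.093, and 0.126 for G2/M). The G2/M call also ended without scrambled array A (adjusted p = 0.0967) or CKS1B shRNA array C (0.110). The actin 3'/5' ratio was 12.4 on array B and 2.93 on array C, against 1.05 to 1.66 on the scrambled arrays. The 18S rRNA control read 3979 on CKS1B shRNA array C and 3216 on scrambled array C, against 139 to 1055 on the other arrays.

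Taken over all arrays, histones and outputs of the MEK-ERK pathway passed camera as higher at the preset correlation, and ribosome biogenesis as lower. These calls are among those that other splits of the arrays matched in number. The histone shifts were -0.07, 0.825 and 0.66 on CKS1B shRNA arrays A, B and C, and -0.62 to 0.43 on the scrambled arrays. Those of MEK-ERK outputs were 0.64, 0.77 and 0.01, against -0.57 to 0.33. Those of ribosome biogenesis were 0.06, -1.97 and 0.15, against -0.05 to 0.17. CKS1B shRNA array A lay within the scrambled range for histones, array C for MEK-ERK outputs, and both for ribosome biogenesis. Of the replication-dependent histones with H1.0, 11 of 12 genes were higher, with a median log2 difference of 0.31 (camera adjusted p = 0.0171, and 0.757 with an estimated correlation). H2BC5 read 1598 ± 499 and 3496 ± 1083 (log2 1.12, adjusted p = 0.933). Of the MEK-ERK pathway outputs, 8 of 12 were higher (median 0.38, adjusted p = 0.0343, and 0.757 with an estimated correlation). SPRED1, a feedback inhibitor of Ras signalling, read 424 ± 99.8 and 871 ± 165 (log2 1.02, adjusted p = 0.933). Of the ribosome biogenesis genes, 17 of 21 were lower (median -0.63, adjusted p = 0.0481, and 0.792 with an estimated correlation). NOP14, a ribosomal small-subunit assembly factor, read 2139 ± 553 and 1145 ± 753 (log2 -1.19, adjusted p = 0.933). Its log2 difference was -0.43 without CKS1B shRNA array B, which read 305, and the groups overlapped. Without CKS1B shRNA array B, with its actin 3'/5' ratio of 12.4, none of these 3 lists passed. Their adjusted p was 0.198 for histones (median 0.28), 0.158 for MEK-ERK outputs (median 0.23) and 0.717 for ribosome biogenesis (median -0.05, mean 0.03 with the test upward). Without both arrays of letter B, histones (0.0374) and MEK-ERK outputs (0.0431) passed as higher. The histone call also ended without scrambled array A (0.180) or CKS1B shRNA array C (0.139). The MEK-ERK call ended without scrambled array A (0.0700), scrambled array C (0.103) or CKS1B shRNA array A (0.136), and that of ribosome biogenesis without scrambled array A (0.0967).

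Without CKS1B shRNA array B, proteasome subunits, heat shock proteins and housekeeping genes passed camera as higher and stromal markers as lower, and none of these lists passed in the main comparison of 6 arrays. With an estimated correlation none of these 4 calls held (adjusted p = 0.511 for each without array B). Of the proteasome subunits, 24 of 27 were then higher (median log2 difference 0.40, adjusted p = 1.06e-06). With 6 arrays 23 of 27 were lower (median -0.36, adjusted p = 0.308), since array B lay at -1.97 against 0.39 and 0.32 on arrays A and C. With array weights, which count array B for little, they passed as higher with 6 arrays (adjusted p = 0.0169), and they passed as lower without CKS1B shRNA array A (adjusted p = 0.0167). PSMB4, a subunit of the proteasome core, read 14230 ± 913 and 26600 ± 8044 over 3 arrays each (log2 0.86, adjusted p = 0.933), 1 of the 4 subunits that were higher with 6 arrays. PSMD6, of the regulatory particle, read 5801 ± 383 and 3979 ± 2874 (log2 -0.99, and -0.07 without array B). Of the heat shock proteins, 10 of 11 were higher without array B (median 0.55, adjusted p = 0.00166), and 4 of 11 with 6 arrays (median -0.10, test upward, adjusted p = 0.710). Of the housekeeping genes, 10 of 11 were higher without array B (median 0.22, adjusted p = 0.00883), and 6 of 11 with 6 arrays (median 0.22, mean -0.04, adjusted p = 0.599). All 6 stromal markers tested were lower without array B (median -0.60, adjusted p = 0.0484), and 5 of 6 with 6 arrays (median -0.54, adjusted p = 0.196). Their shifts were -0.62 and -0.52 on CKS1B shRNA arrays A and C. On scrambled arrays A, B and C they were -0.55, -0.03 and 0.50, so array C lay within the scrambled range. ACTA2, smooth muscle actin, read 927 ± 162 and 512 ± 322 with 6 arrays (log2 -1.09, and -0.41 without array B, which read 155). After quantile normalization without array B, chosen after the data were seen, the adjusted p was 0.145 for the proteasome, 0.284 for heat shock proteins, 0.823 for housekeeping genes and 0.128 for stromal markers.

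**Figure D3:**
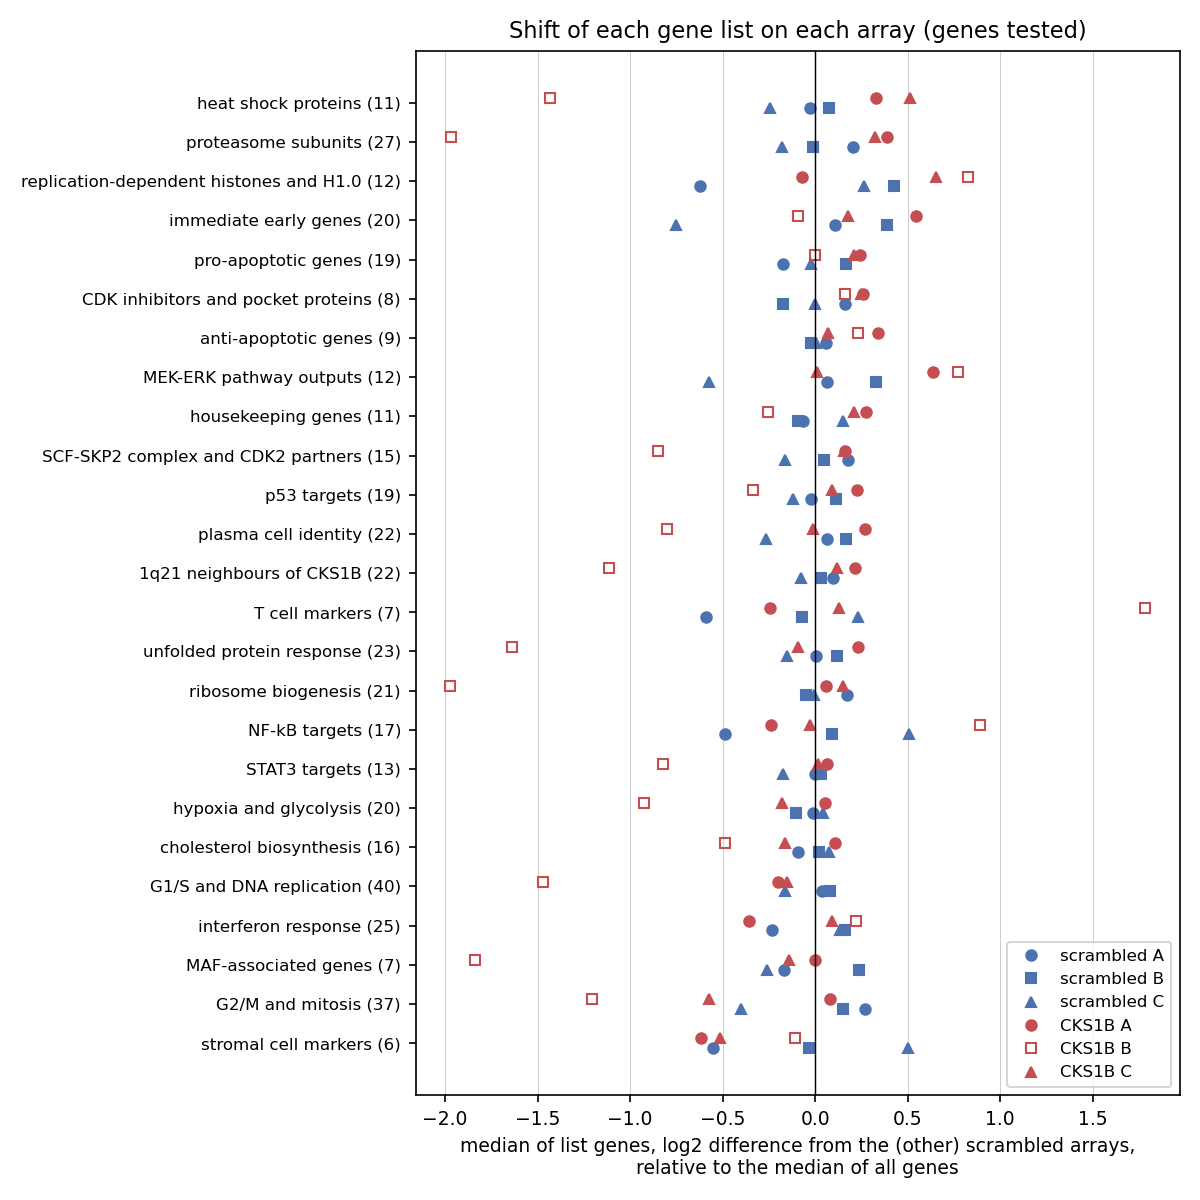
Median log2 difference of each list's genes on each array from the mean of the scrambled arrays (for a scrambled array, the other 2), relative to all genes, for the 25 lists tested, with the number of genes in brackets. CKS1B shRNA array B (open squares) lies farthest from 0 in most lists, at -1.97 for the proteasome, while arrays A and C (filled red) lie at 0.39 and 0.32.

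The p53, apoptosis and plasma cell lists did not pass. Of the p53 targets, 12 of 19 were lower (adjusted p = 0.618). SESN1, a stress-induced inhibitor of mTORC1 signalling, read 931 ± 107 and 221 ± 167 (log2 -2.47, adjusted p = 0.933, and -1.50 without CKS1B shRNA array B, which read 28.7). Of the pro-apoptotic genes, 11 of 19 were lower (median -0.04, mean 0.03, test upward, adjusted p = 0.599), and of the anti-apoptotic genes 5 of 9 were higher (adjusted p = 0.351). Of the plasma cell identity genes, 13 of 22 were lower (adjusted p = 0.670). MZB1, a chaperone of antibody secretion, read 2829 ± 535 and 1233 ± 820 (log2 -1.43, adjusted p = 0.933), and XBP1, a transcription factor of plasma cells, read 6888 ± 1317 and 4318 ± 1763. All 7 of the MAF-associated genes tested were lower with 6 arrays (adjusted p = 0.119), and 5 of 8 without array B (adjusted p = 0.881). MAF read 7262 ± 881 and 9830 ± 8820, and its log2 difference went from -0.19 to 0.86 without array B. For CCND2, a cyclin of G1, it went from -0.12 to 0.42.

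Apart from MEK-ERK outputs and ribosome biogenesis, the stress, signalling and metabolic lists did not pass either in the main comparison. Of the unfolded protein response genes, 17 of 23 were lower (median -0.52, adjusted p = 0.0593), and of the hypoxia and glycolysis genes 17 of 20 (median -0.42, adjusted p = 0.0593). On CKS1B shRNA array B these lists lay at -1.64 and -0.93, and without it their adjusted p was 0.657 and 0.653. The unfolded protein response passed without CKS1B shRNA array A (adjusted p = 0.00234), without a filter (0.00474) and with centred arrays (0.0472). Hypoxia and glycolysis passed as lower without a filter (0.0283), with the mean of probe sets (0.0319) and with quantile normalization without array B (0.0201). With an estimated correlation neither list passed, at 0.792 for the unfolded protein response and 0.757 for hypoxia and glycolysis (0.618 with quantile normalization without array B). ASNS, asparagine synthetase, read 1300 ± 125 and 644 ± 606.5 (log2 -1.59, and -0.62 without CKS1B shRNA array B, which read 99.4). ANKRD37, a hypoxia-induced gene, read 955 ± 142 and 450.5 ± 47.6 (log2 -1.05, adjusted p = 0.933). Of the STAT3 targets 9 of 13 were lower (adjusted p = 0.224), with SOCS2, a suppressor of cytokine signalling, at 746 ± 98.3 and 386 ± 64.4 (log2 -0.93, adjusted p = 0.933). Of the cholesterol biosynthesis genes 12 of 16 were lower (adjusted p = 0.275). Of the interferon response genes 15 of 25 were lower (median -0.14, test upward, adjusted p = 0.867), and of the NF-kB targets 10 of 17 (median -0.32, mean 0.02, adjusted p = 0.867). Of the immediate early genes 11 of 20 were higher (median 0.08, mean -0.07, test upward, adjusted p = 0.599), and the list passed as higher without both arrays of letter B (0.00238). Of the 1q21 neighbours of CKS1B, 16 of 22 were lower (adjusted p = 0.5).

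Markers of other blood cells did not pass. Of the T cell markers 5 of 7 were higher (median 0.58, adjusted p = 0.599), with a shift of 1.78 on CKS1B shRNA array B against -0.24 and 0.13 on arrays A and C. Only 3 myeloid and 3 erythroid markers were bright enough to be counted, too few for a test. All 3 myeloid markers were lower (median -0.13), with S100A8 at 425 ± 176.5 and 301 ± 16.6, and 2 of the 3 erythroid markers were higher (median 0.02), with HBB at 349 ± 80.0 and 293 ± 15.1.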

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

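The tests on CKS1B shRNA array B reported here were chosen after its values were seen. Some control probe sets that the comparison of genes does not use read above every scrambled array, by at least 1.5 times, on CKS1B shRNA arrays B and C. The actin 3'/5' ratio was 12.36 on array B and 2.93 on array C, against at most 1.66 on the scrambled arrays. The GAPDH 3'/5' ratio was 4.7 on array B, against at most 1.17. The hybridization control CreX-3 read 34971.8 on array B and 55458.4 on array C, against at most 19207.3. Another probe set for the same control, r2-cre-3, read 469.1 on array B and 80313.2 on array C, against 15652.6 to 26450.1 on the scrambled arrays. The median log2 ratio between the 2 series of probe sets for the hybridization controls was 1.75 on array B, against -0.47 at most on the scrambled arrays. Groups of 3 arrays are too small for a test of single outlying arrays.

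CKS1B shRNA array B correlates at 0.577 to 0.610 with the other arrays, and a response to the CKS1B shRNA as the reason is argued against by CKS1B shRNA arrays A and C, whose lowest correlation with a scrambled array is 0.879. Degraded RNA or labelling biased to the 3' end may be part of the cause, since the actin ratio of 12.36 and the GAPDH ratio both exceed those of all other arrays. Probe sets for the same hybridization control also disagreed there (34971.8 for CreX-3, 469.1 for r2-cre-3), so the ratios alone do not establish degradation. Degradation or such labelling is not the whole cause: the hybridization controls are added after labelling, and their ratio of 1.75 lies far outside the range of the other arrays (-0.67 to -0.47). A scrambled sample under the wrong label is not the whole cause either, since the highest correlation of the array with a scrambled array is 0.61, below the 0.889 or more between scrambled arrays. Whether the sample on it was a knockdown cannot be told apart by CKS1B, because 4.8% of 500 equally bright genes read at or below CKS1B there, against 0% on the other CKS1B shRNA arrays and 58.2% or more on the scrambled arrays.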

How the results depend on the processing

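CKS1B was lower in every alternative that kept its probe set (it has none without a suffix for shared sequence), with a log2 difference between -4.47 and -3.59 when an array or a letter was left out. It passed the threshold without CKS1B shRNA array B (-3.63), without both arrays of letter B (-3.59), with array weights (-3.80, adjusted p = 2.81e-05) and with quantile normalization without array B (-3.68, adjusted p = 0.00126). The last of these, an estimated correlation or a block without array B, and leaving out both array B and scrambled array C were chosen after the data were seen. The count of genes went from 0 in both directions to 1 higher and 3 lower with array weights, which gave array B a weight of 0.086 (CKS1B, RDX, SLC39A10 and NCKAP1). It was 1 higher and 1 lower with quantile normalization without array B (FTH1P5 and CKS1B), and 0 to 3 higher and 0 to 3 lower when an array or a letter was left out. Only CKS1B passed without letter B.

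The count of lists, 2 higher and 3 lower, became 0 and 0 with an estimated correlation, with fry, and with an estimated correlation without array B. Lists higher numbered 1 with the filter at the 70th percentile, quantile normalization, array weights or the mean of probe sets, and 0 with only unshared probe sets or with quantile normalization without array B. The histone call ended with the filter (adjusted p = 0.0682), array weights (0.2) and unshared probe sets (0.228), and the MEK-ERK call with quantile normalization (0.0762), array weights (0.124), the mean of probe sets (0.101) and unshared probe sets (0.228). With array weights the 1 list higher is the proteasome. Lists lower numbered 5 without a filter, and 2 with the filter at the 70th percentile, quantile normalization, eBayes without the trend, array weights or only unshared probe sets. Ribosome biogenesis lost its call in 4 of these (adjusted p = 0.198, 0.062 without the trend, 0.92 with array weights, 0.265 with unshared probe sets). When an array or a letter was left out there were 0 to 6 lists higher and 1 to 5 lower. The adjusted p of the G1/S list was 0.757 with an estimated correlation, 0.754 with fry and 0.511 with an estimated correlation without array B, and 1.97e-05 to 0.174 when an array or a letter was left out, the last without letter B. For G2/M it was 0.757, 0.754 and 0.741 in the same settings, 0.0762 with quantile normalization, and 2.76e-05 to 0.126 when an array or a letter was left out. All other alternatives but the block without array B, given last, kept both calls.

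The proteasome list turned from lower to higher with array weights (adjusted p = 0.0169), without array B (1.06e-06), without letter B (3.06e-05) and without array B and scrambled array C (0.00186), and ranged from 1.06e-06 to 0.744 when an array or a letter was left out. Ribosome biogenesis turned upward, uncalled, without array B (0.717), without letter B (0.753) and with an estimated correlation without array B (0.88), stayed downward without array B and scrambled array C (0.821), and ranged from 0.00225 to 0.753 when an array or a letter was left out. CTSC turned to 1.58 without array B through another probe set, and lay between -0.6 and 1.58 when an array or a letter was left out. Apart from what fewer arrays or another probe set bring, the cause was not tested. Of 1743 alternatives of named genes, 30 were stronger, 2 reversed and 58 changed sign with no call on either side. Of 647 alternatives of lists, 48 were weaker, 25 stronger, 9 reversed and 100 changed sign with no call on either side.

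With the letter as a replicate block, 0 genes passed and 355 had an unadjusted p under 0.05 in limma. The called lists passed, and so did the unfolded protein response (adjusted p = 0.0292), for 2 higher and 4 lower, and CKS1B stayed at -4.02. Only the arrays of letter A correlated best with each other. The deviations of a letter's 2 arrays correlated at 0.40, -0.08 and -0.08 for A, B and C. Outlying CKS1B shRNA array B enters these, so they do not decide pairing. Without array B the values were 0.30 for A and 0.29 for C, from only 2 pairs whose CKS1B shRNA deviations mirror each other. The replicate block without array B rests on these pairs with 1 residual degree of freedom, and its rate of false calls was not tested, so what the letters share is left open. It gave 62 genes higher and 38 lower, CKS1B at -3.59, CTSC at 1.54, and 7 lists higher and 1 lower. The adjusted p was 0.0716 for G1/S and for G2/M, 0.000107 for the proteasome (upward) 0.836 for ribosome biogenesis (upward), 0.0261 for histones and 0.0304 for MEK-ERK outputs. Dim genes are limited by the signal over background, since the filter removed values under about 146.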

Other observations

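The probe sets, normalization without CKS1B shRNA array B, splits of 5 arrays and tests of explanations here were chosen after the results were seen, except the tests of list shifts on single arrays and of the splits of the 6 arrays. Where a gene has several probe sets, these offer a further reading of the values without CKS1B shRNA array B. The other 2 probe sets of RDX lay lower by log2 differences of -0.996 and -1.005, beside -1.80 for the one used. All 3 probe sets of MFN1 lay between -1.60 and -1.24, and the 3 of FLI1 between -1.58 and -1.002. Both probe sets of GPC6 were higher (1.42 and 1.69), as were both of YES1 (1.04 and 1.36). For SKP2 the differences were -1.14, -0.55 and -0.32. Of the 6 probe sets of XIAP, 5 were higher (0.48 to 1.25) and the dimmest lay at -0.30. The other probe set of NCKAP1, near the filter with a scrambled mean of 148, lay at -0.11. CTSB, a lysosomal protease like CTSC, had 5 probe sets, all higher (0.10 to 1.61), and none was tested by a list fixed beforehand.

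The lists of G1/S and of G2/M were lower in the CKS1B shRNA arrays. Without CKS1B shRNA array B both medians still lie at or below the 0.02 percentile of random lists matched on mean expression. Random lists leave out the spread between arrays and the correlation between genes of a list. That correlation was estimated at 0.246 for G1/S and 0.293 for G2/M with 6 arrays. Whether the compressed scale of array B is the whole cause is therefore not decided. Without both arrays of letter B neither call held in camera (adjusted p = 0.174 for G1/S and 0.126 for G2/M). An intensity-dependent difference between arrays as the whole cause is argued against by quantile normalization without array B, where both lists pass with an adjusted p of 2.85e-06 (0.424 for G1/S and 0.618 for G2/M with an estimated correlation), though with all 6 arrays that normalization ended the G2/M call (0.0762). Dependence on a single CKS1B shRNA array cannot be told apart from a shared fall: array A lies within the scrambled range for G2/M (0.081) and just below it for G1/S, and array C the other way round. With an estimated correlation neither list passed, and no measurement of the cell cycle itself was used here.

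Proteasome subunits, heat shock proteins and housekeeping genes were higher without CKS1B shRNA array B. Random lists matched to them on mean expression had medians of 0.27, 0.22 and 0.28, against -0.04 over all genes. An intensity-dependent difference between arrays may account for much of the shift, because quantile normalization ended all 3 calls, with 0.145 as the lowest adjusted p. Among those random lists the housekeeping genes lay at the 32.6 percentile, the proteasome at 95.8 and heat shock proteins at 98.8. The smallest shift on arrays A and C was 0.212 and every shift lay above all scrambled arrays, so the rise did not rest on a single array. The lists were picked by their camera calls on these same arrays, so the shifts are no separate support for a rise. A biological rise of proteasome and heat shock genes stays open.

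The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest other 0, and since any split gives at least 0 (10 of 10), this count tests nothing. For lists the real split gave 5 and the highest other 7, with 5 of the 10 splits giving at least as many. The 5 arrays without CKS1B shRNA array B also make 10 splits of 2 against 3. The real split gave 6 genes and the highest other 0, so 1 of the 10 splits gave as many, which is again too few splits for a share under 0.05. For lists the real split of these 5 arrays gave 6, and scrambled arrays A and C against the rest also gave 6. By unadjusted p, the split of scrambled array C with CKS1B shRNA array C against the rest gave 1909 genes, more than the 1217 of the real split, which points to a structure of the samples. Both are of letter C, and their 18S rRNA control read 3216 and 3979, against 139 to 533 on the other 3 of these arrays. The 2 arrays of letter A against the rest gave 672 genes by unadjusted p. A scrambled array with a CKS1B shRNA array of another letter gave 128 to 210. The fit of these 5 arrays that gave 6 genes had no term for the letter.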
